A study of Arabidopsis thaliana with 6 samples.

How the data were processed

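Wild-type Arabidopsis thaliana plants were grown on soil with sand under a day temperature of 20 °C and a night temperature of 16 °C, 80% relative humidity and 300 µmol of light per square metre and second, per the labels. One group received ambient air and the other ambient air with 3 ppm NO, at all hours until harvest at 4 weeks, and RNA came from whole rosette leaves. Cy3-labelled cRNA was made from 10 ng of RNA and hybridised to one-colour Agilent arrays, per the labels' protocols. The NO content of the ambient air was not given in the sources used here. The 6 samples fall into 2 groups of 3 by their titles. The titles number the arrays of both groups 1 to 3, while the source names number the NO arrays 2 to 4, and the text uses the title numbers.

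The deposited scanner files hold spot intensities on a linear scale, and their processed signal was background-corrected by Agilent Feature Extraction, version 10.7.3.1 per the file headers and version 10.5 per the submitters' processing notes. The deposited series matrix holds the authors' log2 values. Set against the scanner files, its columns were close to log2 signals shifted to the 75th percentile of each array and centred on each probe's median over the 6 arrays, but not identical (Pearson r across probes 0.997 to 1.000, with all 43601 probe medians at 0). The share of probes within 0.01 on the log2 scale was 92.9%, 98.0% and 21.1% on the ambient arrays and 48.2%, 48.3% and 96.4% on the NO arrays. Its column medians were 0.03, 0.04 and -0.02 for the ambient arrays and 0.02, -0.07 and -0.03 for the NO arrays, and it served as an alternative. Outlier, well-above-background and saturation marks of spots were taken from the deposited files as the scanner software set them, per the file headers.

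Here the main values were log2 of the processed signal minus its 75th percentile on each array, which lay between 716 and 1320. Control spots and spots marked as non-uniform or population outliers (5 to 18 gene spots per array) were left out, and spots of 1 probe were averaged. Of 43603 probes, 34285 matched 1 locus in a RefSeq gene table for the assembly TAIR10.1 through their transcript accession, and 9318 did not match and are reported apart. No coordinate is given, because the file headers name an older genome build than that table. A gene was represented by its probe of highest mean log2 signal, which gave 25383 genes, 6919 of them with several probes. Of 5629 genes with several tested probes, 52 had probes that passed the test in opposite directions. A gene was tested where its probe was well above background on all 3 arrays of at least 1 group. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values given with ± are the log2 change and its SE from limma, and folds are the same change on the linear scale. A gene not well above background on any array of a group is given as a bound.

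The 30 gene lists (429 loci, of which 2 stand in more than 1 list) were fixed before the data were examined, as were the main tests of genes and lists, the alternatives apart from one, and the rule for naming genes. The rule took the 10 largest rises and 10 largest falls among genes with a symbol whose groups did not overlap, 7 genes of NO and nitrate metabolism, and up to 4 members with the smallest adjusted p from each list with at least 3 members past the threshold or a call in camera. Lists with at least 5 tested members were compared with all other genes by camera of limma at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. The lists were photosynthesis, nitrate uptake and reduction, primary nitrate response, ammonium and amide assimilation, phytoglobins, S-nitrosoglutathione reduction and antioxidants, detoxification and mitochondrial stress, jasmonate, salicylic acid, ethylene, glucosinolates, flavonoids and anthocyanins, leaf senescence, phosphate starvation, sulfur, iron, hypoxia, cold and abscisic acid, heat shock, cell expansion, cell cycle, flowering time, circadian clock, reference genes, and markers of root, flower, shoot meristem, seed, guard cells and vascular cells. For the list tests, 12 genes with a missing value on an array were left out.

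Tested on simulated arrays with the spread of these 6 (18602 genes, 200 of them shifted), the comparison of 3 ppm NO with ambient recovered 6% of genes shifted by 0.25 on the log2 scale, 70% at 0.5, and 100% at 1 and at 2, and it called 12 unshifted genes. Of 5 shifted lists 5 were called, and of 25 unshifted lists 0. The simulated genes were drawn independently, so these list counts do not cover lists whose genes are correlated. Far fewer genes were shifted than passed in the data, so the recovered shares of small shifts do not carry over to the data.

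The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, cyclic loess normalization (the one chosen after seeing the data), no filter on dim probes, a filter for all 6 arrays, outlier spots kept, the mean of all probes of a gene, every probe on its own, an intensity trend with robust variances, the series matrix values, replicate numbers as a block, and each array left out in turn. The mean spot signal was not used here, so normexp ran on the median spot signal and the median local background. Each slide held 1 group, so slide as a block could not be fitted. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files.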

Results

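The transcriptome of Arabidopsis thaliana rosettes grown in ambient air was compared with that of rosettes grown in the same air with 3 ppm nitric oxide (NO) added. The title of the series concerns NO as a source of nitrogen for plants, so the question addressed was which transcripts differed after 4 weeks of continuous exposure, with nitrogen and phytoglobin genes examined one by one. Total RNA from whole rosette leaves of wild-type plants was hybridised to 6 one-colour Agilent arrays, 3 per group, which the labels describe as coming from 3 independent biological experiments. Each array carried 61657 gene spots, and no gene spot was saturated. Well above background were 65.2% to 66.8% of them on the ambient arrays and 68.5% to 72.0% on the NO arrays. The lowest signal well above background was 16.1 to 21.2 on the ambient arrays and 13.9 to 16.0 on the NO arrays. The number of arrays limits the precision of every value. All 3 ambient arrays lay on one slide and were scanned together, and all 3 arrays of the NO group lay on the other slide, so slide and group cannot be told apart in any comparison given here. Of 10 probes for spike-in control transcripts, 7 had signal above the background floor on all arrays of a group, and these 7 were brighter on every array of the NO slide, by 54.7 times for the brightest of them.

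In rosettes grown in 3 ppm NO, most tested genes of the photosynthesis, jasmonate, glucosinolate, phosphate starvation and nitrate uptake and reduction lists were higher, and most of the flavonoid and anthocyanin and leaf senescence lists were lower. These lists passed in camera at a preset correlation between genes, and none passed with an estimated one (adjusted p of 0.0775 to 0.340 with an estimated correlation). SAG12, a cysteine protease gene used as a marker of leaf senescence, was 27.6-fold lower, and LDOX, TT7 and DFR, which encode enzymes of anthocyanin and flavonoid synthesis, were 11.3-fold, 10.6-fold and 8.54-fold lower. PDF1.2, a defensin gene induced by jasmonate and ethylene, was 19.4-fold higher, and LOX2, a lipoxygenase gene of jasmonate synthesis, was 7.66-fold higher. Of 18614 genes tested with limma, 10839 (58.2%) passed an adjusted p of 0.05, of which 4806 were higher and 6033 were lower in NO. Most changes in the main fit were small, since 7337 of the genes that passed (67.7%) changed by less than 1.5-fold. With a change of at least 2-fold, 927 genes were higher and 372 were lower. In 12425 genes (66.8%) the 3 arrays of one group all lay above the 3 of the other, where chance gives 10%. The median absolute log2 difference between 2 arrays was 0.0864 to 0.0916 within a group and 0.266 to 0.285 between groups. The 2-fold counts fell to 460 higher and 188 lower when the background was corrected with normexp.

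**Figure D1:**
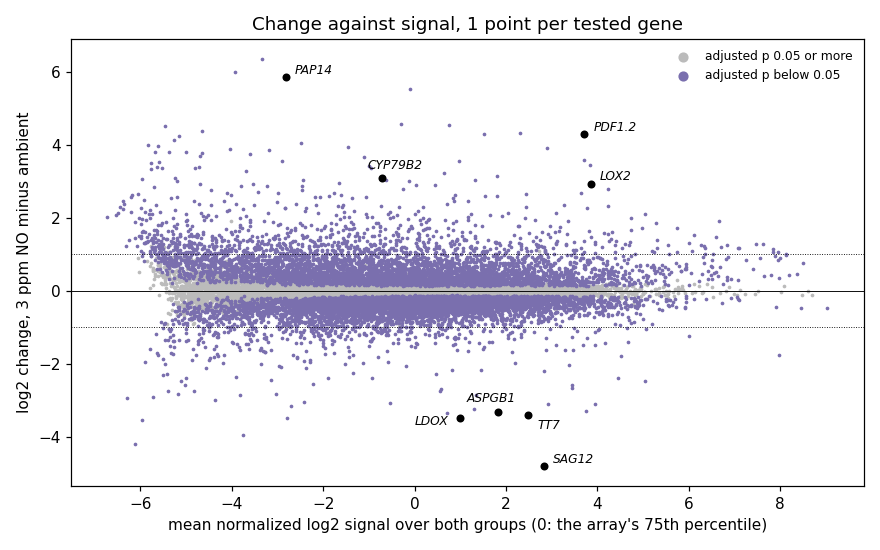
Each point is 1 of the 18614 tested genes, with the mean normalized log2 signal of both groups on the x axis (0 is the 75th percentile of an array) and the log2 change at 3 ppm NO minus ambient on the y axis. Purple points passed an adjusted p of 0.05, dotted lines mark a 2-fold change, and the labelled genes include PDF1.2 at 4.28 and SAG12 at -4.79.

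Among genes with a symbol, the largest rise was that of PAP14, a purple acid phosphatase gene, at 5.85 ± 0.15 on the log2 scale (SE, n = 3 per group), although only 1 of its 3 ambient arrays was well above background and normexp gave 3.56. The other 9 of the 10 largest rises included the defensin genes PDF1.2c (4.32 ± 0.09), PDF1.2b (4.29 ± 0.08), PDF1.2 (4.28 ± 0.07) and PDF1.3 (3.90 ± 0.07). These defensin genes are close paralogs, and whether their probes share signal was not tested, which leaves the value of each one uncertain. The remaining 5 were not well above background on any ambient array and have only a bound. Their place among the 10 rests on fitted changes from those ambient signals. A gene outside the 10, such as CYP79B2 at 8.56-fold, can exceed their bounds. CYP94B1, which encodes a jasmonate-catabolising cytochrome P450, was at least 8.34-fold higher, and 4CL8, annotated by its symbol as a 4-coumarate:CoA ligase family member, was at least 5.63-fold higher. PGL5 was at least 5.05-fold higher, RAP2.6, a transcription factor gene of the ERF family, was at least 5.03-fold higher, and scpl1, a serine carboxypeptidase-like gene, was at least 3.24-fold higher. A bound sets the mean of the NO group against the ambient mean of, per array, the lowest signal well above background or the gene's own if that was higher. With normexp, whose offset compresses low signals, the log2 changes of these 5 genes were 0.89 to 1.501, below their bounds.

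Of the 10 largest falls, 6 were of genes of flavonoid or anthocyanin synthesis or its regulators. After SAG12 (-4.79 ± 0.06) came LDOX (-3.50 ± 0.07) and TT7 (-3.40 ± 0.05), followed by ASPGB1, an asparaginase gene, at -3.33 ± 0.09. DFR (-3.09 ± 0.05) and TT8 (-3.08 ± 0.08), a bHLH regulator of anthocyanin synthesis, fell by similar amounts. ADS4, a fatty acid desaturase-like gene, was at -3.03 ± 0.07, and the purple acid phosphatase gene PAP20 was at -2.99 ± 0.44, with 2 of its 3 NO arrays well above background. MYB11, a regulator of flavonol synthesis, was at -2.85 ± 0.19. The dim genes PAP20 and MYB11 fell by less with normexp, at -1.20 and -1.57, as did ADS4, at -2.08. Last, the anthocyanin malonyltransferase gene AT5MAT was at -2.85 ± 0.07. Adjusted p over these 20 genes was at most 0.00141 in limma, and the highest was that of PAP20.

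Of the phytoglobin genes, whose products can oxidise NO to nitrate, AHB1 rose and the other two did not pass the test over all genes. AHB1, which is also known as a hypoxia-induced gene, was 2.05-fold higher (log2 change 1.03 ± 0.06, adjusted p = 3.40e-05 in limma). AHB2 was at 0.14 ± 0.06 with an adjusted p of 0.0670, and GLB3 at 0.16 ± 0.06 with an adjusted p of 0.0630, both with all 3 NO arrays above all 3 ambient arrays. Adjusted over the list alone, 3 of the 3 passed. Over 19 refits under other settings the adjusted p ran from 0.0246 to 0.354 for AHB2 and from 0.0219 to 0.358 for GLB3, which passed in 4 and 5 of them; without NO replicate 1 that of GLB3 was 0.0401. GSNOR, the S-nitrosoglutathione reductase gene, was 1.19-fold higher (0.25 ± 0.05, adjusted p = 0.00483), and it did not pass with the source-name numbers as a block (adjusted p = 0.0948) and was at 0.16 with quantile normalization.

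Nitrate assimilation genes rose. NIA1 and NIA2, which encode nitrate reductase, were 3.02-fold and 3.12-fold higher, and NIR1, which encodes nitrite reductase, rose by 1.32 ± 0.07 on the log2 scale, although NIA1 was measured on only 2 of the 3 NO arrays because its spot on NO replicate 1 was an outlier. NRT2.5, a high-affinity nitrate transporter gene known to be induced by nitrogen starvation, went the other way and was 2.77-fold lower, and the other members that fell, named after their values were seen, were SLAH3 and NRT1.7. Of 14 tested genes of nitrate uptake and reduction, 9 rose, 3 fell and 2 did not pass. As a list they were called higher than other genes in camera (adjusted p = 0.0273). That call was lost with an estimated correlation between genes (adjusted p = 0.276 with an estimated correlation). Of 12 tested genes of the primary nitrate response, 8 rose, 1 fell and 3 did not pass, with 6 rises under normexp (camera adjusted p = 0.00296, and adjusted p = 0.0839 with an estimated correlation). LBD37 and LBD38, transcription factor genes known to respond to nitrate and to repress anthocyanin genes, were 7.77-fold and 4.77-fold higher, with 2 of the 3 ambient arrays well above background for LBD38 and a log2 change of 0.97 with normexp in place of 2.25. BT1, a nitrate-responsive regulator gene, was 1.55-fold higher, and UPM1, a sirohaem synthesis gene, was also 1.55-fold higher.

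Ammonium and amide genes moved both ways. Of the 20 tested, 6 rose, 9 fell and 5 did not pass, and the list did not stand apart from other genes (camera adjusted p = 0.784). GLN1;4, a cytosolic glutamine synthetase gene, was 2.68-fold lower, GDH3, a glutamate dehydrogenase gene, was 1.77-fold lower, and the asparagine synthetase gene ASN3 was 2.18-fold lower. In contrast ASN1, another asparagine synthetase gene, was at least 3.98-fold higher and was not well above background on any ambient array, and normexp gave a log2 change of 0.71, below that bound. Over the phytoglobin, nitrate and ammonium lists together, 24 of 49 tested genes rose and 13 fell.

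**Figure D2:**
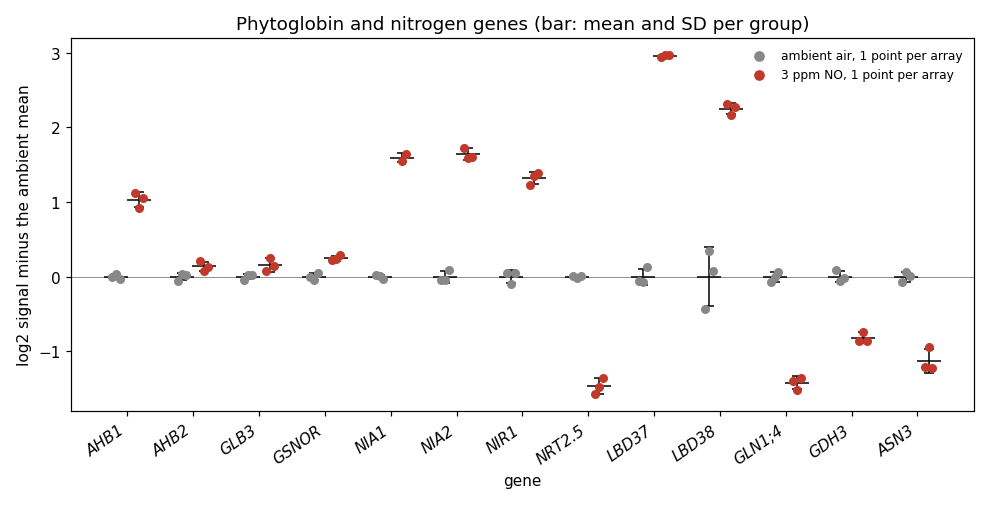
Points are single arrays, grey for ambient air and red for 3 ppm NO, and bars give the mean and SD of each group. The y axis is the normalized log2 signal minus the ambient mean of that gene, and NIA1 has 2 NO points; AHB1, NIA1, NIA2, NIR1, LBD37 and LBD38 lie above the ambient arrays by 1.03 to 2.96, while NRT2.5, GLN1;4, GDH3 and ASN3 lie below them.

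Photosynthesis genes rose together. All 27 tested members of the list passed, with a median log2 change of 1.01 and a range of 0.33 to 1.90, whereas with quantile normalization 24 rose, 1 fell and the median was 0.66. LHCB6 and LHCA2, antenna protein genes of photosystems II and I, were 3.74-fold and 2.52-fold higher, and PSBQ-2, a gene of the oxygen-evolving complex, was 3.65-fold higher. LHCB2.1, a photosystem II antenna gene with near-identical copies, was 3.60-fold higher with its brightest probe, but its other probe went the opposite way, and the mean of its probes gave a log2 change of 0.55 in place of 1.85. In camera the list had an adjusted p of 1.16e-13, which was 0.213 as an adjusted p with an estimated correlation.

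Jasmonate genes also rose in all 17 tested members, with a median log2 change of 1.39, or 0.89 with 16 passing under normexp (camera adjusted p = 1.49e-10, and adjusted p = 0.0775 with an estimated correlation). Beside PDF1.2 and LOX2 they included JAZ9, a repressor of jasmonate signalling that jasmonate itself induces, which was 3.96-fold higher, and the allene oxide cyclase gene AOC1, which was 2.94-fold higher. Of 20 glucosinolate synthesis genes, 18 rose, none fell and 2 did not pass (camera adjusted p = 1.46e-11, and adjusted p = 0.0775 with an estimated correlation). CYP79B2 and CYP83B1, genes of the indole branch, were 8.56-fold and 4.37-fold higher, their regulator MYB34 was 5.94-fold higher, and FMO GS-OX1, a side-chain oxidase gene of the aliphatic branch, was 3.91-fold higher. Salicylic acid defence genes did not pass as a list (camera adjusted p = 0.0632), with 9 of 15 higher, 3 lower and 3 not passing. PR5 and PAD3 were 1.51-fold and 1.67-fold higher, while PR1 and SARD1 were 1.77-fold and 2.00-fold lower (log2 change of PR1 -0.46 with normexp in place of -0.82). Of 14 ethylene genes, 5 rose, 6 fell and 3 did not pass (camera adjusted p = 0.755). ACO1, a gene of ethylene synthesis, was 2.12-fold higher (log2 change 0.67 with normexp in place of 1.08) and ERF2 1.90-fold higher, while ERF104 and ERF5 were 2.05-fold and 1.46-fold lower.

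All 16 tested genes of flavonoid and anthocyanin synthesis fell, with a median log2 change of -2.43 and a range of -3.50 to -0.55 (camera adjusted p = 3.32e-10, and adjusted p = 0.0775 with an estimated correlation). F3H, the flavanone 3-hydroxylase gene, was 5.95-fold lower. Of 15 leaf senescence genes, 10 fell, 2 rose and 3 did not pass (camera adjusted p = 0.00668, and adjusted p = 0.340 with an estimated correlation). SAG29, a sugar transporter gene, was 4.89-fold lower and SAG13 was 2.45-fold lower, whereas SEN1, a dark-inducible gene, was 4.53-fold higher.

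Phosphate starvation genes rose in 13 of 14 tested members, with a median log2 change of 1.29 (camera adjusted p = 8.88e-09, and adjusted p = 0.0775 with an estimated correlation). SRG3, a glycerophosphodiester phosphodiesterase gene, was 6.85-fold higher, the phosphatase gene PS2 was 5.08-fold higher, SQD2, a sulfolipid synthase gene, was 3.03-fold higher, and the acid phosphatase gene PAP17 was 2.68-fold higher. Sulfur assimilation genes did not pass as a list (camera adjusted p = 0.0704), with 8 of 14 higher, 3 lower and 3 not passing. APS1, SERAT2;1 and APR1, which encode enzymes from sulfate to cysteine, were 2.27-fold, 1.81-fold and 1.55-fold higher, while LSU2, a gene induced by sulfur deficiency, was 2.29-fold lower. Iron homeostasis genes were mixed, with 4 of 17 higher, 6 lower and 7 not passing (camera adjusted p = 0.611). The ferritin genes FER1 and FER3 were 1.90-fold lower and 1.34-fold higher, the nicotianamine synthase gene NAS1 was 2.25-fold higher, and the transporter gene YSL1 was 1.40-fold lower.

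Hypoxia genes rose in 11 of 12 tested members, with a median log2 change of 0.65 (camera adjusted p = 2.10e-05, and adjusted p = 0.0775 with an estimated correlation). Beside AHB1 they included the sucrose synthase gene SUS4, the transcription factor gene LBD41 and the plant cysteine oxidase gene PCO1, with log2 changes of 1.31, 1.07 and 0.73. Cold and abscisic acid genes rose in 9 of 14 members and 5 did not pass (camera adjusted p = 0.000198, and adjusted p = 0.0775 with an estimated correlation). COR15B, COR15A, CBF3 and ERD10 were 2.90-fold, 2.82-fold, 1.77-fold and 1.66-fold higher. Of 17 genes of S-nitrosoglutathione reduction and antioxidant enzymes, 5 rose, 4 fell and 8 did not pass (camera adjusted p = 0.562). The catalase genes CAT3 and CAT1 and the iron superoxide dismutase gene FSD1 had log2 changes of 0.59, 0.47 and 0.45, and GR1, a glutathione reductase gene, was at -0.40. The 3 rises did not pass with quantile normalization, where the log2 changes were 0.02 for CAT3, -0.08 for CAT1 and 0.12 for FSD1, and 1 of the 3 probes of CAT1 went down. CAT1 also did not pass when the probes of a gene were averaged (log2 change 0.095, adjusted p = 0.312 in limma). Of 17 detoxification and mitochondrial stress genes, 5 rose, 6 fell and 6 did not pass (camera adjusted p = 0.873), with the glutathione transferase genes GSTF2 and GSTF7 2.54-fold and 2.35-fold higher and GSTU24 2.71-fold lower, beside the transcription factor gene NAC032, which was 2.30-fold lower. Of 7 tested heat shock genes, 1 rose, 3 fell and 3 did not pass (camera adjusted p = 0.489). HSP70, HSP90.1 and MBF1C were 1.78-fold, 1.32-fold and 1.30-fold lower and DREB2A was 1.39-fold higher (log2 change 0.48, or 0.79 when the probes of a gene were averaged), although HSP90.1 did not pass when the probes of a gene were averaged (adjusted p = 0.136).

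Of 9 cell expansion genes, 8 rose and 1 fell (camera adjusted p = 0.000255, and adjusted p = 0.0775 with an estimated correlation). The expansin genes EXPA8, EXPA1 and EXPA11 rose by 1.82, 1.63 and 0.65 on the log2 scale and the xyloglucan endotransglucosylase gene TCH4 by 1.18. Of 15 cell cycle and DNA replication genes, 11 rose and 4 did not pass (camera adjusted p = 0.00449, and adjusted p = 0.213 with an estimated correlation). KN, a cytokinesis syntaxin gene, was 1.69-fold higher, the replication gene MCM5 1.93-fold and the ribonucleotide reductase gene TSO2 1.34-fold higher, and with normexp the log2 change was 0.44 for KN in place of 0.76 and 0.42 for MCM5 in place of 0.95. CYCB1;2, a mitotic cyclin gene, was at least 1.801-fold higher, and it did not pass with normexp (adjusted p = 0.248). The median log2 change of the cell cycle list was 0.74, or 0.67 with its 3 bounded members at their bounds, but with normexp it was 0.20 and 5 of the 15 members rose. Markers of vascular cells moved beside these lists. Of 9 phloem and xylem markers, 6 rose and 3 fell (camera adjusted p = 0.0688), and the genes XCP2, IRX1 and IRX5 of xylem and SEOR1 of sieve elements were 2.35-fold, 1.98-fold, 1.82-fold and 1.66-fold higher. Of 3 tested shoot meristem markers, 2 rose, STM and KNAT1 (named after their values were seen), with log2 changes of 0.50 and 0.31.

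Markers of other cell types gave no uniform shift. Of 7 guard cell and stomatal lineage markers, 5 fell, 1 rose and 1 did not pass (camera adjusted p = 0.221). FAMA, SLAC1 and MYB60 were 1.60-fold, 1.47-fold and 1.26-fold lower, and AT1G22690 was 1.91-fold higher. Of 10 tested flower and inflorescence markers, 4 rose, 1 fell and 5 did not pass (camera adjusted p = 0.755). SEP2, PI and SHP1 were 1.55-fold, 1.35-fold and 1.34-fold higher, and AMS was 2.05-fold lower with 1 of its 3 NO arrays well above background. Over all refits the adjusted p ran from 0.00327 to 0.141 for AMS and from 0.00690 to 0.508 for SHP1. The fall of AMS did not pass when ambient replicate 1 (adjusted p = 0.0820), ambient replicate 3 (0.0580), NO replicate 2 (0.0727) or NO replicate 3 (0.0840) was left out, and the rise of SHP1 did not pass without NO replicate 1 (0.0524) or 2 (0.0584). With normexp SEP2, SHP1 and AMS did not pass (adjusted p of 0.0585, 0.508 and 0.111). Of the 8 root markers 1 was tested, with a log2 change of -0.24 that did not pass, and none of the 3 seed storage markers was well above background on all arrays of a group.

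Of 16 flowering time genes, 6 rose, 2 fell and 8 did not pass (camera adjusted p = 0.164). FT, which encodes the mobile floral signal, was 1.47-fold higher, SOC1 and SPL9 were both 1.42-fold higher, and FUL was 1.51-fold lower. Of 16 circadian clock genes, 6 rose, 5 fell and 5 did not pass (camera adjusted p = 0.755). The morning genes LHY, PRR9 and CCA1 were 1.97-fold, 1.49-fold and 1.41-fold lower, and PRR5, which peaks later in the day, was 2.45-fold higher. Of 7 tested reference genes, 1 passed, the elongation factor gene AT5G60390, which was 1.15-fold lower, named after its value was seen, and which did not pass when its probes were averaged (adjusted p = 0.395) or with the source-name numbers as a block (0.141), while its log2 change was -0.21 in the main fit, -0.33 with cyclic loess and -0.64 with quantile normalization. The median log2 change of the 7 was -0.01, and its sign differed between scalings, from -0.08 with median scaling to 0.01 with normexp.

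In total 10 of 26 tested lists were called higher and 2 were called lower than other genes in camera with a preset correlation of 0.01 between genes. None of these 12 calls held with an estimated correlation, where 0 lists passed after adjustment and 8 had an unadjusted p under 0.05. The estimated correlation was under the preset 0.01 for cell expansion (-0.0651), cold and abscisic acid (-0.000548) and primary nitrate response (-0.00404). In camera their unadjusted p still rose, from 7.85e-05, 5.34e-05 and 0.00102 to 0.0148, 0.0127 and 0.0258. Correlation between genes therefore does not account for these lost calls. The estimated setting also takes its degrees of freedom from the few arrays, which raises p at any correlation. A lost call is therefore not evidence of correlation within a list, and the share due to each was not tested. Every other called list had a higher estimate, from 0.0623 for hypoxia to 0.555 for photosynthesis. Adjusted over the list alone, 19 glucosinolate genes rose in place of 18, 11 cold and abscisic acid genes in place of 9 and 3 shoot meristem markers in place of 2, and apart from the phytoglobins no other list changed its count.

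**Figure D3:**
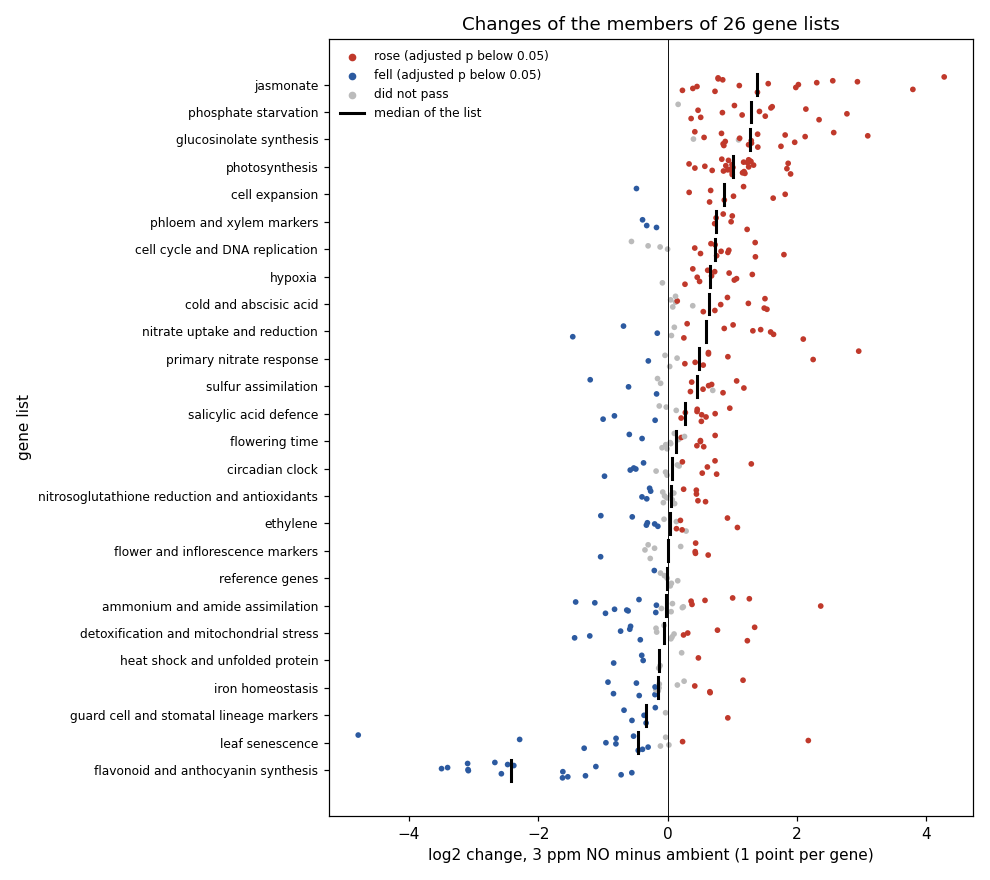
Each point is 1 tested gene of the list named on the y axis, placed at its log2 change (3 ppm NO minus ambient), and the black bar is the median of the list. Red genes rose and blue genes fell at an adjusted p under 0.05, and grey genes did not pass; medians run from -2.43 in flavonoid and anthocyanin synthesis to 1.39 in the jasmonate list.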

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

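The probes for the E1A spike-in controls, transcripts made to be added before labelling, enter none of the group comparisons and differed between the groups. The brightest of them, E1A_r60_1, had a geometric mean signal of 1057 on the ambient arrays and 57803 on the NO arrays, a ratio of 54.7. Of the 10 spike-in probes, 7 lay above the lowest gene signal well above background on all arrays of a group, and these 7 were brighter on every NO array than on every ambient array. The other 3 lay near background and give no direction. The slope of the spike-in line in the scanner files was 0 on all 3 ambient arrays and 0.963, 1.026 and 0.997 on the NO arrays. Why the spike-ins differed was not tested. The array scaling uses gene signals only, and the 75th percentile of gene signals on the ambient arrays (830 to 876) lay within the range of the NO arrays (716 to 1320).

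Probes that matched no locus in the gene table gave a signal outside the comparisons of named genes. Of 3738 such probes tested with limma, 1752 passed an adjusted p of 0.05, and with a change of at least 2-fold 236 were higher and 44 were lower at 3 ppm NO. These probes are unnamed here.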

How the results depend on the processing

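Over 19 refits of the comparison, the count of genes past the threshold (10839) stayed within 1.5 times except with the source-name numbers as a block, and all 12 list calls kept their direction and their side of the threshold in every refit. Leaving out 1 array gave 9479 to 9736 genes, 906 to 948 of them at least 2-fold higher and 364 to 393 at least 2-fold lower, and 12 lists each time. Of 116 named genes that passed, 9 lost the call or changed sign in at least 1 refit. Of the genes past the threshold, 9970 passed in the same direction with cyclic loess, which was chosen after seeing the data, and 13 passed in the opposite direction with quantile normalization and 9 with the mean of all probes. Of the nitrogen and phytoglobin genes, 31 to 39 passed, against 37. The log2 change of 24 named genes shrank by over 1.5 times or changed sign in at least 1 refit, 18 of them with normexp.

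With normexp, 460 genes were at least 2-fold higher and 188 at least 2-fold lower; its offset of 50 draws low signals together, and the cause was not tested further. Testing every probe gave 7678 higher and 1620 at least 2-fold higher, over 29702 probes in place of 18614 genes. Camera with an estimated correlation, whose degrees of freedom come from the few arrays and limit its power, called 0 lists. Its adjusted p was 0.0775 for jasmonate, glucosinolates, flavonoids, phosphate starvation, hypoxia, cold and abscisic acid, and cell expansion, 0.0839 for primary nitrate response, 0.213 for photosynthesis and for cell cycle, 0.276 for nitrate uptake and reduction and 0.340 for senescence. Fry, which does not compare a list with other genes, called 23 lists, and those that camera did not call were salicylic acid (6.48e-05, Up), sulfur (8.77e-05, Up), vascular markers (0.000410, Up), ammonium (0.00176, Down), guard cells (0.00414, Down), heat shock (0.00635, Down), ethylene (0.00996, Up), flowering time (0.0170, Up), iron (0.0304, Down), detoxification (0.0448, Down) and reference genes (0.0448, Down), while the clock turned down (0.0761).

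Some lists passed in camera only under another setting, and the cause was not tested. Salicylic acid passed with normexp (0.0439), median scaling (0.0373), the filter on all 6 arrays (0.0486) and every probe (0.00613). Sulfur passed with normexp (0.0281), median scaling (0.0392) and no filter (0.0327). Vascular markers passed with normexp (0.0297), median scaling (0.0273), no filter (0.0390), the filter on all 6 arrays (0.0486), the mean of probes (0.0326) and the source-name block (0.0484). Antioxidants passed with every probe (0.00841), where each gene counts once per probe. Lists far from the threshold changed sign, meaning camera's direction against other genes and not that of the median, again with the cause not tested. They were reference genes with normexp (0.948), no filter (0.979), all 6 arrays (0.992), the mean of probes (0.922), every probe (0.946), the source-name block (0.949) and without ambient replicate 1 (0.966), the only 1 of the 6 refits with an array left out that changed sign (range of the 6 0.900 to 0.980), flower markers with normexp (0.948), antioxidants (0.290) and ethylene (0.945) with quantile, and detoxification with every probe (0.523). Among named genes, CAT1 alone changed sign, to -0.0818 with quantile normalization.

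Deviations from the group means gave no sign of pairing by title number. They correlated at -0.0795, -0.0395 and 0.0453 in the 3 pairs, and 1 of 3 NO arrays correlated best with its own number. Under the source-name numbers the correlations were 0.0198 and -0.118. With 3 arrays per group, these few values cannot exclude pairing. With the title numbers as a replicate block 10066 genes passed, and with the source-name numbers, which leave 1 array of each group without a partner, 7141 passed, 3696 of them lower. Slide as a block was not run, because each slide held 1 group. Signal over background limits the dimmest genes, and 218 rises and 14 falls have only a bound. On every NO array a larger share of gene spots was well above background than on any ambient array. That difference between the slides bears on these counts of bounds.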

Other observations

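Carbonic anhydrase genes, singled out after their values were seen, held some of the larger rises among bright genes. CA1, the main chloroplast enzyme of leaves, was 11.9-fold higher at 3 ppm NO (log2 change 3.57 ± 0.08, n = 3 per group), and its 8 probes gave log2 changes of 2.97 to 3.89. CA2 was 6.39-fold higher, ACA1 2.31-fold higher and BCA4 1.25-fold higher, while BCA3 was 1.21-fold lower. BCA5 and BCA6 did not pass in limma (adjusted p of 0.541 and 0.383). CA1, CA2, ACA1 and BCA4 also rose and BCA3 also fell with quantile, median and cyclic loess scaling and with normexp (adjusted p of BCA3 up to 0.0448).

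Genes grouped by the stem of their symbol, in 193 groups of at least 8 tested members, gave 25 groups that passed camera at the preset correlation and none that passed with an estimated one (adjusted p of 0.554 or more). With its degrees of freedom taken from 6 arrays, the estimated setting has little power over 193 groups. Its lack of calls therefore says little about correlation within these groups. The 6 groups given here were picked after their values were seen. Rises were found in 9 of 11 beta-galactosidase genes, with no fall (BGAL, median log2 change 0.76), in 10 of 12 fasciclin-like arabinogalactan genes, with 1 fall (FLA, 0.62), and in 9 of 13 auxin-responsive SAUR genes, with 2 falls (1.40, or 0.38 with normexp). Translation initiation factor genes (EIF) fell in 17 of 21 members and rose in 1 (median -0.29), genes with the stem TIM, most of which encode mitochondrial import proteins, in 11 of 13 with 1 rise (-0.43), and ECT genes, which encode RNA-binding YTH-domain proteins, in 8 of 11 with no rise (-0.42). The medians of these groups kept their sign under every scaling tried. Adjusted p in camera was 0.00410 for BGAL, 0.00836 for FLA and EIF, 0.0245 for SAUR, 0.0325 for TIM and 0.0224 for ECT.

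The pattern is the large number of genes past the threshold, 10839 of 18614, and the tests given next, cyclic loess among them, were chosen after that count was seen, and for those on slides and on technical repeats the criterion was also set after their own values were seen. The other 9 splits of the 6 arrays into 3 and 3 called 0 genes in limma, with 120 to 242 at an unadjusted p under 0.05 against 11792, so that 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each of those 9 splits mixes the groups, so the difference between groups enlarges its residual variance and lowers its count. Their counts are therefore no reference for chance. Against hybridisation differences of single probes as the whole cause, in genes that passed with a change under 1.5-fold and had another tested probe, that probe went the same way in 90.12% of 2499 genes (95% exact binomial interval 88.9% to 91.3%, which takes genes as independent), although it passed in the same direction in only 55.3%. Whether the probes of a gene overlap in sequence was not checked, and overlapping probes could share such differences. The count after cyclic loess normalization was 98.1% of the main count, and 9970 genes passed in the same direction as in the main fit. A count cannot exclude a trend with signal, because such a trend can change which genes pass. Of the genes with at least a 2-fold change, 71.4% were higher in the main fit, 70.2% with cyclic loess and 64.1% with quantile normalization. Slide, scan and labelling cannot be told apart from NO, since 0 of the 2 slides held both groups. Arrays of a group being close to technical repeats also stays open. The variance of probe means between arrays was 1.54 times the variance that repeat spots give such a mean in the ambient group. In the NO group it was 3.57 times.

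The morning clock genes LHY, PRR9 and CCA1 were lower while PRR5 was higher, and a candidate explanation is a later time of day at harvest in the NO group. In further genes, 5 evening-phased and 10 morning-phased ones, the median log2 change was 0.15 and 0.02, a difference of 0.13 in the direction of that hypothesis (two-sided exact permutation p = 0.512). The test does not decide it, since members went both ways, and a biological difference in the clock was not tested apart from it.

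Nitrate reductase genes rose while NRT2.5, GLN1;4 and ASPGB1 fell, and a hypothesis is that a higher nitrogen supply lowered starvation responses. Autophagy genes, which nitrogen starvation induces, were listed before their values were seen. Of 11, 7 fell, 2 rose and 2 did not pass, with a median log2 change of -0.35, but the list missed the threshold in camera (p = 0.0662, or p = 0.206 with an estimated correlation). In the scan by symbol stem, 10 of 19 ATG genes fell and 2 rose, with a smaller median of -0.20 (camera adjusted p = 0.155). The hypothesis is left open, as is the slide, which holds one group only.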
